A study of Mus musculus with 18 samples.

How the data were processed

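The authors' table gives FPKM per gene for 18 libraries, and it was used as deposited, with 0 columns of no sample. Per the submitters' processing notes, CASAVA 1.8.2, STAR 2.4.0 and Cufflinks 2.1.1 were used upstream. The genome build is not given in the sources used here, so no coordinates are reported. Of 23474 gene identifiers 22671 matched a symbol in GENCODE M21 and 803 did not, and no symbol occurred more than once. Groups were taken from the labels, with 3 libraries for each of 3 diets in 2 tissues.

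Values were tested as log2(FPKM + 1), since FPKM is not a count and read numbers were not used here. A gene entered the fit of a tissue when at least 3 of its 9 libraries reached 1 FPKM, which kept 13762 adipose and 10670 liver genes. Each tissue was fitted in limma 3.58.1 (R 4.3.3) with a mean per diet and empirical Bayes variances with trend and robust options. Each of 3 contrasts and an F test over the 3 diets was adjusted by Benjamini-Hochberg within its fit, at 0.05. Tissue differences were contrasts of contrasts in a fit of 18 libraries over the 10042 genes kept in both tissues. Gene lists, 35 in all and compiled from general knowledge, were tested by camera at a preset correlation of 0.01, where at least 5 genes were kept, with adjustment over the lists of a contrast. The filter, the scale, the tests, the contrasts, the rule for naming genes and the repeats with other settings, save those given as later, were chosen before the data were examined. Nonoverlap was counted where every library of a diet lay above every library of the other, which chance gives in 10% of genes for 3 against 3 and in 20% for 3 against 2.

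Genes were named by rule. For high-fat against normal diet and for extract against high-fat diet, up to 10 rises and 10 falls were the largest changes among called genes with nonoverlapping libraries, and up to 5 each way for extract against normal diet and for tissue differences. Where fewer were called, the genes of smallest unadjusted p were named as not passing, up to 5 each way. Up to 4 members of a list with the smallest p were also open to naming, and 16 genes of fat, glucose and inflammation were fixed for naming where measured. Some genes that the rule names are not reported here. Predicted, clone-named, pseudogene, small RNA and mitochondrial entries were passed over. Using the same rule for the adipose fit without ND 1 was decided after seeing the data, as were the genes shown for tissue content, for high levels in HFD of both tissues and for the clock.

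The fit was tested on simulated data with 100 genes changed by log2 1 and 100 by log2 2. These were built from the spread in the fit of all 9 libraries of a tissue, adipose ND 1 included. In adipose tissue 0% and 31% of these were recovered for high-fat against normal diet, and 4% and 42% for extract against high-fat diet, with 4 and 0 false calls. In liver 63% and 99%, and 79% and 97%, were recovered, with 8 and 10 false calls. With no gene changed, 0 were called in either tissue. Correlations between contrasts that share the HFD libraries were compared with 100 simulations of unchanged groups.

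The repeats used an added 0.1 in place of 1, no filter, a filter at 5 FPKM, equal FPKM totals, quantile scaling, the replicate number as a block, a plain variance prior, 1 fit of 18 libraries, only the compared diets in the fit, each library left out in turn, and for lists an estimated correlation and fry. After the data had been seen, a correction for gene length and GC content, fits without the 3 adipose libraries with testis transcripts or the 2 liver libraries with most muscle transcripts, and list tests at equal FPKM totals were added. Libraries were also split into other groups of the same sizes, in all 10 ways for 3 against 3 and in 100 drawn ways elsewhere. Tables and plots were made in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.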

Results

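RNA was sequenced from epididymal fat and liver of male C57BL/6J mice at 17 weeks of age, after 12 weeks on a normal diet (ND), a high-fat diet (HFD) or the high-fat diet with 0.25% green tea extract (GT). Each tissue and diet had 3 libraries, 18 in all, and the table listed 23474 genes in FPKM. The labels do not say that each library came from a separate mouse, so the p-values measure the spread between these samples, which may be partly technical. FPKM totals ran from 527904 to 608819 in 8 adipose libraries and reached 1002765 in adipose ND 1, while liver totals ran from 680168 to 930139. Read numbers were not analysed here. Relative depth was read from the steps between values under 0.1 FPKM, where 11.42% to 53.78% of values lay on the steps against 3.65% to 7.12% at shifted positions, and adipose ND 1 lay 0.65 log2 units under adipose ND 2. In what follows, levels are mean ± SD in FPKM (n = 3 libraries), changes are log2 ± SE from limma on log2(FPKM + 1), and adjusted p is Benjamini-Hochberg. The added 1 understates changes of genes with low FPKM.

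Adipose ND 1 held RNA of testis and epididymis. The spermatid genes Tnp1 and Prm1, which pack sperm DNA, stood at 28802 and 18708 FPKM in it, and the epididymal genes Lcn8 and Gpx5 at 8812 and 6364. The fat hormones adiponectin (Adipoq) and leptin (Lep) stood at 202 and 7.97 FPKM there, against 2781 and 1826, and 322.7 and 316.6, in ND 2 and ND 3. Of 24 testis markers, 23 reached 10 FPKM in ND 1, 18 in ND 3 and 16 in HFD 1, and at most 8 in each other adipose library. Tnp1 reached 707.3 in ND 3 and 604.2 in HFD 1. HFD 2 carried the epididymal gene Crisp1 at 1172. Rank correlations within adipose tissue ran from 0.892 to 0.981 without ND 1 and from 0.676 to 0.829 with it, and those within liver ran from 0.961 to 0.979. Muscle markers summed to 164 FPKM in liver HFD 2, 64.9 in liver GT 3, 34.4 in liver HFD 3 and at most 3.44 in the other liver libraries. The abundant genes mt-Co1 and Alb were listed at 0 in liver HFD 3, and mt-Co1 also in liver GT 3, so a value of 0 can be a failed estimate. Every adipose comparison is given with all 9 libraries and then without ND 1, a choice made after the data had been seen.

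**Figure D1:**
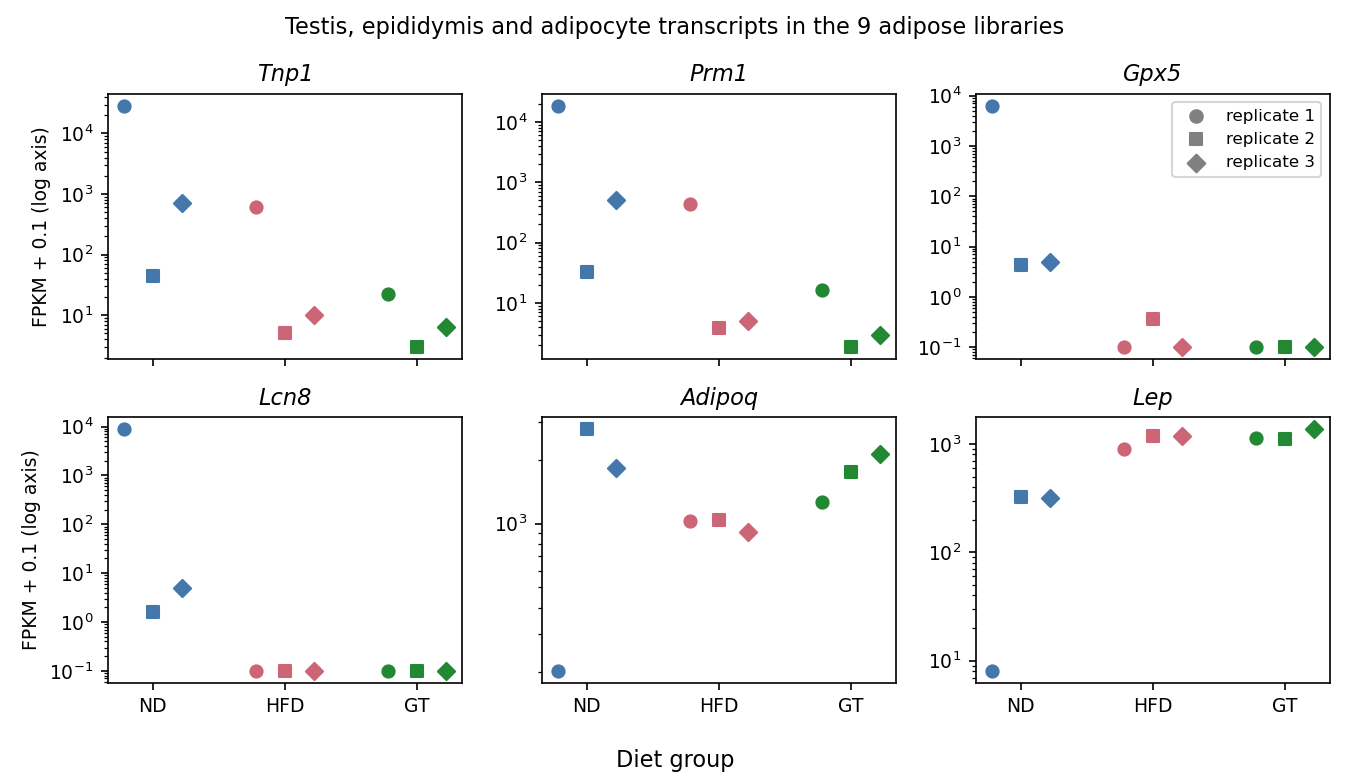
Expression of Tnp1, Prm1, Gpx5, Lcn8, Adipoq and Lep in the 9 adipose libraries, as FPKM + 0.1 on a log axis. Circle, square and diamond mark libraries 1, 2 and 3 of each diet.

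In adipose tissue of mice on the high-fat diet, the macrophage genes Gpnmb, Mmp12 and Trem2 were among the largest rises over the normal diet. Gpnmb, a phagocyte glycoprotein, rose from 4.02 ± 1.86 to 844 ± 132 FPKM (log2 7.45 ± 0.52, adjusted p = 0.00214). The macrophage elastase Mmp12 rose from 5.25 ± 4.84 to 1059 ± 286 and the lipid receptor Trem2 from 4.16 ± 2.96 to 312 ± 69.9 (log2 7.90 ± 0.84 and 6.04 ± 0.57). The proton pump subunit Atp6v0d2 rose by 6.13 ± 0.43, the protease Adam8 by 5.84 ± 0.57, the ubiquitin-like Ubd by 5.52 ± 0.56, Rgs1 by 5.45 ± 0.41, the integrin Itgax by 5.33 ± 0.54 and the stress factor Atf3 by 5.30 ± 0.59. Il1rn, which blocks interleukin-1, was listed at 0, 0.7004 and 0.1545 FPKM on the normal diet and at 56.91, 58.21 and 74.34 on the high-fat diet. The chemokine Ccl2 rose from 2.76 ± 2.26 to 40.9 ± 7.76 FPKM (log2 3.74 ± 0.57, adjusted p = 0.0103) and the macrophage marker Adgre1 from 10.3 ± 8.43 to 222 ± 33.0 (log2 4.88 ± 0.85, adjusted p = 0.0164). Tnf went from 0, 0.2073 and 0.1673 to 2.109, 1.911 and 2.193 FPKM (adjusted p = 0.0136). Among the falls, the adipocyte protease Cfd (adipsin) went from 3583 ± 514 to 313 ± 53.5 FPKM (log2 -3.52 ± 0.36, adjusted p = 0.00436) and angiotensinogen (Agt) from 109 ± 10.4 to 12.8 ± 3.92 (log2 -3.04 ± 0.40). Gsta4, which clears lipid aldehydes, fell from 28.7 ± 10.9 to 3.20 ± 0.679, and Eif4ebp3, Ccdc73, Dcst1, Dpm1, Adig and Spaca6 also fell. For Eif4ebp3, Ccdc73 and Dcst1 the normal diet levels of 14.7 ± 12.6, 29.7 ± 21.8 and 17.7 ± 11.4 included ND 1, and the means of ND 2 and ND 3 were 7.42, 17.4 and 11.7. ND 3 held testis RNA too, so these means may still include it. Calls of Dcst1 and Spaca6 ended without ND 3, among other libraries. Whether testis RNA gave part of these falls was not tested. The lens gene Crygn was listed at 0 in each HFD library and at 14.46, 6.886 and 5.519 on the normal diet. Leptin (log2 3.48 ± 1.24, adjusted p = 0.173), Adipoq (adjusted p = 0.985), Pck1 (adjusted p = 0.439), Scd1 (0.27, adjusted p = 0.9), Cd36 (adjusted p = 0.376) and the lipogenic Fasn (adjusted p = 0.362) did not pass with ND 1 in the fit.

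Among adipose gene lists, 11 differed between high-fat and normal diet at the preset correlation, 8 up and 3 down, and 0 lists in any comparison or tissue held with an estimated correlation. Of 19 macrophage genes 11 rose and 0 fell, 16 adjusted over the list alone, with Cd68 up 4.84 (adjusted p = 0.582 with an estimated correlation). Of 21 cytokine genes 10 rose, 15 adjusted over the list alone, among them Saa3, Tgfb1 and Ccl3 (adjusted p = 0.582 with an estimated correlation). Matrix genes rose in 8 of 28, 18 adjusted over the list alone, with Timp1 up 3.36, Mmp3 2.69 and Mmp13 1.62 (adjusted p = 0.612 with an estimated correlation). Cell-cycle genes rose in 7 of 20, 13 adjusted over the list alone, Mki67, Ccna2 and Mcm6 by 1.81, 1.98 and 1.84 (adjusted p = 0.612 with an estimated correlation). Cholesterol synthesis genes rose in 6 of 22, 11 adjusted over the list alone, with Dhcr7 up 2.31 and Msmo1 up 1.57 (adjusted p = 0.582 with an estimated correlation). The antigen-presenting class II genes rose in 3 of 7 and the mast cell and neutrophil genes in 3 of 6, with 7 and 5 adjusted over the list alone, and H2-DMb1 and Cpa3 were up 2.31 and 1.85 (adjusted p = 0.582 with an estimated correlation for each). Epididymal genes had a list median of -5.634 and 0 of 5 passed, which follows the content of ND 1 (adjusted p = 0.63 with an estimated correlation).

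With all 9 adipose libraries, 777 of 13762 genes differed between high-fat and normal diet, 726 up and 51 down, and 3785 (27.5%) had nonoverlapping libraries against 10% by chance. The count was 3527 without ND 1, 310 without HFD 1, 262 without HFD 2, 59 without HFD 3 and 416 without GT 2. Without ND 2 it was 2789 and the majority turned, with 1167 up and 1622 down (41.8% up against 93.4%), in a fit where ND 1 had more weight. Of 44 genes named in this text and called with all 9 libraries, 17 held whichever library was left out, among them Gpnmb, Mmp12, Trem2 and Cfd. Leaving out HFD 3 ended 27 of these calls, HFD 2 ended 13, HFD 1 ended 9, GT 2 ended 3, and ND 3, GT 1 and GT 3 ended 2 each. Ccl2 and Agt had adjusted p = 0.0641 and 0.052 without HFD 3, and Adgre1 had 0.0864, 0.0644 and 0.0589 without HFD 3, HFD 2 and HFD 1.

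Without ND 1, the fall of adipocyte genes on the high-fat diet became part of the called set in adipose tissue. Of 12859 genes 3527 differed, 2290 up and 1237 down, and 6459 (50.2%) had nonoverlapping libraries against 20% by chance for 3 against 2. Cyp2e1, an oxidase of ethanol and fatty acids, fell by 4.07 ± 0.48 (adjusted p = 0.00162). Acsm3, Cfd, Eci3, Agt and Adgrg2 fell by 3.65, 3.63, 3.27, 3.09 and 2.97, as did Fam13a, Crygn and Mycl, and Pck1, which makes glycerol backbone in fat, fell by 3.05 ± 0.30. Leptin rose by 1.76 ± 0.18 (adjusted p = 0.00118) to 1094 ± 169 FPKM, while Adipoq fell by 1.19 ± 0.26 (adjusted p = 0.0118) and Scd1 by 1.41 ± 0.26 (adjusted p = 0.00542). Fasn, Cd36, Pparg, Srebf1 and Ppara did not pass in either fit. Gpnmb, Mmp12, Trem2, Tm4sf19 and F7 were up 7.18, 6.91, 6.47, 5.28 and 5.07, and Ccl2 and Adgre1 up 3.03 and 3.78. In the adipocyte list 11 of 21 fell and 2 rose, 12 and 2 adjusted over the list alone, with Adrb3 down 2.33, Retn 1.91 and Acvr1c 2.06 (adjusted p = 0.45 with an estimated correlation). Genes of the citrate cycle and branched-chain amino acid breakdown fell in 14 of 26, 18 adjusted over the list alone, with Ivd, Pccb and Bckdha down 1.41, 1.08 and 0.86 (adjusted p = 0.385 with an estimated correlation). Lipolysis genes fell in 8 of 11 and rose in 1, likewise 8 and 1 adjusted over the list alone (adjusted p = 0.385 with an estimated correlation). Matrix genes rose in 20 of 28 and fell in 0, 20 and 1 adjusted over the list alone, Postn and Mmp2 by 1.73 and 1.96 (adjusted p = 0.385 with an estimated correlation).

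**Figure D2:**
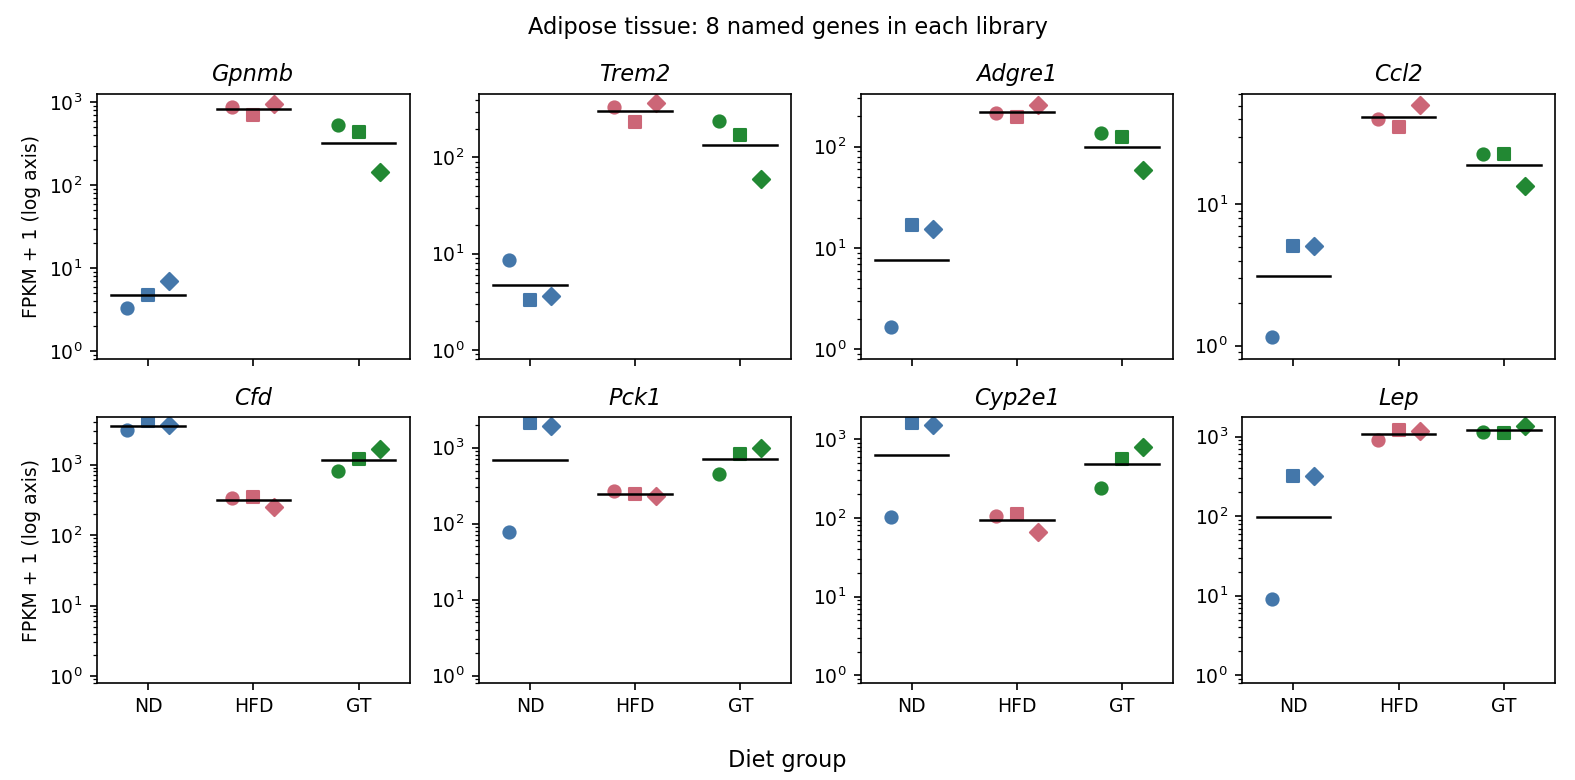
Adipose FPKM + 1 on a log axis for Gpnmb, Trem2, Adgre1, Ccl2, Cfd, Pck1, Cyp2e1 and Lep on normal diet, high-fat diet and high-fat diet with extract. Symbols are libraries and bars are means on the log scale (n = 3).

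Between the extract and the high-fat diet alone, 0 adipose genes differed by limma with all 9 libraries, while 467 of 13762 had unadjusted p under 0.05 and 4832 (35.1%) had nonoverlapping libraries against 10% by chance. With only these 2 diets in the fit, 920 genes were called, 416 up and 504 down. The smallest p-values among rises not passing were those of the zinc transporter Slc39a7, Cfd (1.92 ± 0.36), the myosin Myh14 (1.01 ± 0.22), Serpina3b and Agt, and among falls those of Siglec15, the mast cell protease Cpa3 (-1.78 ± 0.32), Fbln1, Pianp and Cck, each at adjusted p = 1. Slc39a7 was at 1.035, 1.685 and 1.731 FPKM with the extract and at most 0.1441 in each other adipose library. In liver its low values varied within a diet, at 0, 0.05217 and 1.323 on the normal diet and 2.369, 0 and 1.332 with the extract. Gpnmb stood at 844 ± 132 on the high-fat diet and 370 ± 203 with the extract, and Mmp12 at 1059 ± 286 and 315 ± 158, neither passing. By list, 15 differed, 9 up and 6 down, and each of these lists had 0 genes called. The adipocyte, lipid droplet and lipolysis lists tested up at the preset correlation, with medians of 0.756, 0.376 and 0.587 (adjusted p = 0.626 with an estimated correlation for each). The cell-cycle and macrophage lists tested down, with medians of -0.83 and -0.712 (adjusted p = 0.626 with an estimated correlation for both). By fry 0 lists passed. The respiratory chain list tested up with a median of 0.091 and a mean of -0.005 (adjusted p = 0.626 with an estimated correlation), and its call ended without HFD 1, HFD 2 and GT 1 (adjusted p = 0.0844, 0.112 and 0.0568).

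Leaving out ND 1 gave 218 adipose genes between extract and high-fat diet, 115 up and 103 down, of 12859, and 4744 (36.9%) had nonoverlapping libraries against 10% by chance. Cfd, Pck1 and Cyp2e1, lower on the high-fat diet than on the normal diet, rose with the extract. Cfd rose from 313 ± 53.5 to 1224 ± 434 FPKM (log2 1.92 ± 0.26, adjusted p = 0.0412), Pck1 from 246 ± 19.9 to 748 ± 275 (1.53 ± 0.27) and Cyp2e1 by 2.36 ± 0.43 to 531 ± 279. The carbonic anhydrase Car3 rose from 2732 ± 345 to 8161 ± 2594, the desaturase Scd1 from 3835 ± 642 to 9410 ± 2478, the triglyceride enzyme Gpat3 from 13.9 ± 1.34 to 44.3 ± 16.4 and the droplet protein Plin5 from 6.24 ± 0.341 to 17.5 ± 4.31. Pmepa1 rose from 80.2 ± 4.61 to 229 ± 22.8, Serpina3b by 1.49, Ifi27l2a by 1.35 and the fatty acid receptor Ffar2 by 1.29. The falls were led by Scand1, Rnaset2b and Rnaset2a (-3.09, -2.80 and -2.34), followed by Cox5b (-1.80), Cpa3 (-1.78), Siglec15 (-1.77), Timp1 (-1.72 ± 0.32), H2afj, Basp1 and Pianp. Ccl2 (-1.12, adjusted p = 0.053), Adgre1 (adjusted p = 0.096), Adipoq (adjusted p = 0.119) and Lep (adjusted p = 0.609) did not pass. In the adipocyte list 5 of 21 rose and 0 fell, 13 adjusted over the list alone (adjusted p = 0.217 with an estimated correlation). Among lipolysis genes 3 of 11 rose, 7 adjusted over the list alone with 1 down, led by Lipe at 0.92 and Aqp7 at 0.78 (adjusted p = 0.195 with an estimated correlation). Mast cell and neutrophil genes fell in 4 of 6, also 4 adjusted over the list alone, with Tpsb2, Mcpt4 and Cma1 down 1.47, 1.38 and 1.54 (adjusted p = 0.195 with an estimated correlation). Matrix genes fell in 5 of 28, 15 adjusted over the list alone with 2 up, among them Postn, Mmp3 and Mmp2 (adjusted p = 0.411 with an estimated correlation). No macrophage gene passed, and 8 of 19 fell adjusted over the list alone (adjusted p = 0.541 with an estimated correlation).

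In adipose tissue of mice given the extract, macrophage genes such as Gpnmb and Mmp12 were above the normal diet in the fit of all 9 libraries. Gpnmb was higher by 6.07 ± 0.52 (adjusted p = 0.00856), Mmp12 by 6.03 ± 0.84, Ubd by 5.17 ± 0.56, Atp6v0d2 by 4.89 ± 0.43, and the acute-phase gene Saa3 by 5.00 ± 0.37 at 147 ± 70.7 FPKM against 3.31 ± 0.817. Gsta4, Nat8f1 and Med18 were lower by 2.69, 1.83 and 1.34, and the sulfide enzyme Sqor (-1.45, adjusted p = 0.0572) and Ift81 (-1.73, adjusted p = 0.0649) did not pass. Of 13762 genes 88 differed, 84 up and 4 down, and 4016 (29.2%) had nonoverlapping libraries against 10% by chance. The count was 1370 without ND 1, 14 without ND 3, 9 without HFD 1, 7 without HFD 2, 7 without HFD 3, 7 without GT 1, 0 without GT 2 and 147 without GT 3. Without ND 2 it was 2544 and the majority turned, with 622 up and 1922 down, and in the fit of 18 libraries 1350 were up and 1592 down. With only these 2 diets in the fit 0 genes were called, and with the replicate number as a block 3. Of 9 named calls, 9 ended without GT 2, Gpnmb and Saa3 among them, 6 ended without each of ND 3, HFD 1, HFD 2, HFD 3 and GT 1, and 2 without GT 3. Without ND 1 leptin was higher by 1.91 ± 0.18 (adjusted p = 0.00249), Ccl2 by 1.92 ± 0.25, Adgre1 by 2.63 and Trem2 by 5.29, while Acsm3, Adgrg2, Efcab7 and Cfd were lower by 2.95, 2.58, 1.94 and 1.71, as was Fam13a. Pck1 was lower by 1.52 without ND 1 (adjusted p = 0.0194), against 0.05 with all 9 libraries (adjusted p = 0.982). Macrophage genes passed in 5 of 19, 14 adjusted over the list alone (adjusted p = 0.487 with an estimated correlation), and cytokine genes in 2 of 21, 12 adjusted over the list alone (adjusted p = 0.487 with an estimated correlation). By list, 11 differed, 9 up and 2 down.

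In liver, the high-fat diet went with large rises of Cyp2b9 and glutathione transferase genes and a large fall of Hsd3b5. The cytochrome Cyp2b9 rose from 2.13 ± 1.99 to 95.3 ± 41.4 FPKM (log2 5.01 ± 0.62, adjusted p = 0.00203), the glutathione transferase Gsta1 by 4.55 ± 0.61 and Gstm3 from 2.70 ± 0.794 to 30.5 ± 10.4. The steroid enzyme Hsd3b5, high in males, fell from 61.2 ± 16.5 to 0.964 ± 1.4 (log2 -5.17 ± 0.67, adjusted p = 0.00292). The stress hormone Gdf15 rose from 1.36 ± 0.49 to 29.9 ± 6.95 (log2 3.71 ± 0.26, adjusted p = 0.000123). Cfd, which fell in fat, rose in liver from 1.87 ± 1.2 to 136 ± 72.3 FPKM (log2 5.48 ± 0.44). Scand1, Lgals1, Lcn2 and Cyp2a22 rose by 3.65, 3.48, 3.33 and 3.26, and Cyp2a4 was listed at 0.08197, 0.3682 and 0 on the normal diet and at 2.48, 16.44 and 27.46 on the high-fat diet. Serpina1e fell from 927 ± 364 to 72.3 ± 42.3, the organic anion carrier Slco1a1 from 147 ± 62.8 to 17.3 ± 22.2, the complement gene C8b from 116 ± 25.9 to 22.0 ± 8.80 and the leptin receptor Lepr from 11.5 ± 3.25 to 0.812 ± 0.107. Cyp4a12b, Cyp4a31, Egfr, Ehhadh and Socs2 fell by 3.04, 2.28, 2.21, 2.06 and 2.03. Near-identical copies exist for Cyp2b9, Cyp2a4, Gsta1, Cyp4a12b and Serpina1e, so shared reads may blur their values, and the same holds for Saa1, Cyp2a5 and Rnaset2b. Fasn rose from 19.0 ± 3.06 to 73.5 ± 24.4 (adjusted p = 0.00307), Pparg, Srebf1 and Ccl2 rose by 1.21, 0.88 and 1.21, and the glucose-making G6pc fell by 1.18 ± 0.30. Scd1 (adjusted p = 0.807), Cyp7a1 (adjusted p = 0.264), Cd36 (1.04, adjusted p = 0.0698) and Ppara (adjusted p = 0.208) did not pass.

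By list, 15 differed in liver between high-fat and normal diet, 11 up and 4 down. Male-biased genes fell in 9 of 17 and rose in 0, 11 adjusted over the list alone, with a list median of -1.5 (adjusted p = 0.385 with an estimated correlation). Cholesterol synthesis genes rose in 14 of 23, 17 adjusted over the list alone with 1 down, with Fdps, Msmo1, Nsdhl and Hmgcs1 up 2.20, 2.04, 1.83 and 1.64 (adjusted p = 0.385 with an estimated correlation). NRF2 targets, which answer oxidative stress, rose in 12 of 25, 13 adjusted over the list alone, with Gstm1 up 2.06 and Gsta4 up 1.32 (adjusted p = 0.385 with an estimated correlation). Cytochrome P450 and conjugation genes of xenobiotic metabolism rose in 4 of 24 and fell in 4, 5 and 4 adjusted over the list alone, and the list did not pass (median -0.108, mean 0.311, adjusted p = 0.962). Lipid droplet genes rose in 8 of 18 and fell in 1, 10 and 1 adjusted over the list alone, with Plin4, Fabp4 and Fitm1 up 2.86, 1.87 and 1.78 (adjusted p = 0.445 with an estimated correlation). Immediate early genes rose in 6 of 12, 8 adjusted over the list alone, among them Jun, Egr1 and Jund (adjusted p = 0.417 with an estimated correlation). Gluconeogenesis and amino acid breakdown genes fell in 5 of 14, 6 adjusted over the list alone, with Cps1 down 1.94 and Got1 down 1.57 (adjusted p = 0.385 with an estimated correlation). Respiratory chain genes rose in 13 of 29, 15 adjusted over the list alone, with Uqcrq, Cox5a and Cox6c up 1.52, 1.05 and 1.02 (adjusted p = 0.417 with an estimated correlation). Cox5a, at 645 bases, was among the shortest 20% of genes (under 1084), while lengths of the whole list are not given here. Each gene was next set relative to its mean over the 9 liver libraries. The median of the shortest 20% of genes minus that of the longest 20% was then 0.252, 0.523 and 0.156 log2 in the HFD liver libraries. It was -0.329 to -0.018 in the other 6. Peroxisomal and fatty acid oxidation genes under PPARA fell in 6 of 30 and rose in 2, 8 and 2 adjusted over the list alone, with Cyp4a14 down 1.95 (adjusted p = 0.588 with an estimated correlation). Muscle genes had a list median of 1.992 and 0 of 10 passed, which follows the muscle RNA in HFD 2 (adjusted p = 0.588 with an estimated correlation).

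With all 9 liver libraries, 1980 of 10670 genes differed between high-fat and normal diet, 1268 up and 712 down, and 4787 (44.9%) had nonoverlapping libraries against 10% by chance. The count was 571 without ND 1, 511 without ND 3, 460 without HFD 2 and 3367 without GT 3. At equal FPKM totals the majority turned, with 625 up and 877 down. Of 46 named calls, 39 held whichever library was left out. Without ND 1 the calls of Egr1, G6pc, Slco1a1, Socs2 and Srebf1 ended, without ND 3 those of G6pc, Kdr, Slco1a1 and Srebf1, without HFD 2 those of Cox6c, G6pc, Kdr, Slco1a1, Socs2 and Srebf1, and without HFD 3 that of Srebf1.

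**Figure D3:**
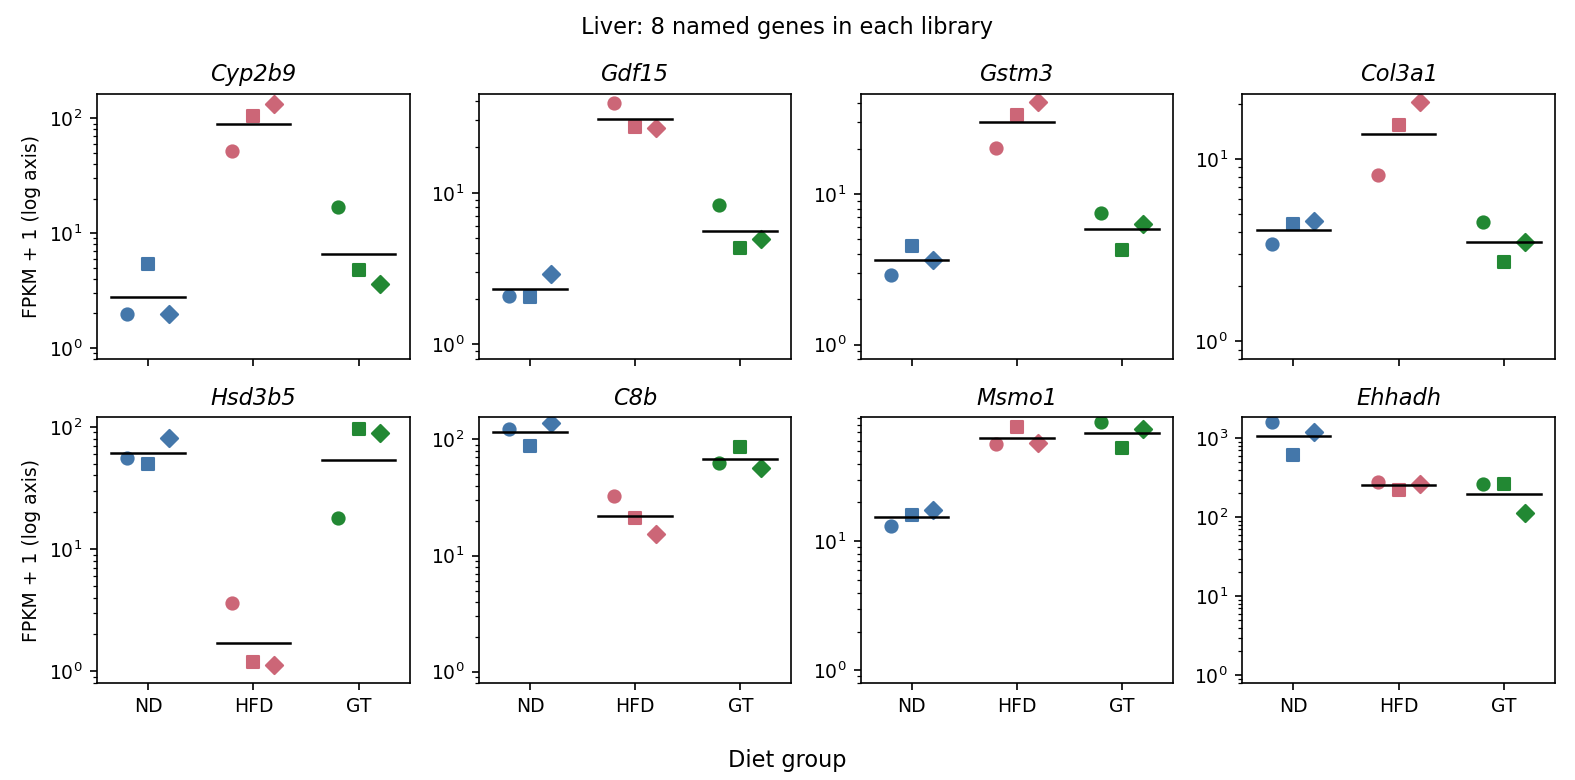
Liver FPKM + 1 on a log axis for Cyp2b9, Gdf15, Gstm3, Col3a1, Hsd3b5, C8b, Msmo1 and Ehhadh on the 3 diets. Symbols are libraries and bars are means on the log scale (n = 3).

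With the extract, 392 liver genes called for the high-fat diet were called in the opposite direction. That number was 138 at equal FPKM totals and 172 without a filter. Hsd3b5 rose from 0.964 ± 1.4 to 66.6 ± 43.2 FPKM (log2 4.99 ± 0.67, adjusted p = 0.00932), and C8b from 22.0 ± 8.80 to 67.5 ± 15.5 (log2 1.62 ± 0.28). Cyp2b9 fell from 95.3 ± 41.4 to 7.42 ± 7.34 (log2 -3.75 ± 0.62), Gdf15 from 29.9 ± 6.95 to 4.86 ± 2.15 (log2 -2.44 ± 0.26, adjusted p = 0.00272) and Gstm3 from 30.5 ± 10.4 to 5.03 ± 1.64. The iron hormone Hamp rose from 265 ± 189 to 1077 ± 315 FPKM, and the growth factor receptor Egfr from 12.5 ± 5.02 to 61.9 ± 42.7. Serpina1e, Cyp4a12b, Gbp11, Ces3b, Mup8 and the anion carrier Slc22a7 also rose. Mup8 is 1 of several near-identical urinary protein genes. Ly6d, Scand1, Gsta1, Wfdc2 and Ifi27l2b fell by 3.25, 2.85, 2.61, 2.37 and 2.18, the cell-cycle brake Cdkn1a from 7.60 ± 4.25 to 0.787 ± 0.383 and Cd63 from 18.1 ± 7.22 to 3.31 ± 0.981. Ccl2 fell from 2.66 ± 0.68 to 0.551 ± 0.398 (log2 -1.26 ± 0.22, adjusted p = 0.015). The fasting hormone Fgf21 fell by 2.07 (adjusted p = 0.00244). Fasn (-0.53, adjusted p = 0.281), Srebf1 (0.54, adjusted p = 0.178), Scd1 (adjusted p = 0.189), Pck1 (adjusted p = 0.908), G6pc (adjusted p = 0.475), Cyp7a1 (adjusted p = 0.441) and Cyp2a4 (adjusted p = 0.0502) did not pass.

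By list, 13 differed in liver between extract and high-fat diet, 3 up and 10 down. Matrix genes fell in 11 of 20, 19 adjusted over the list alone with 1 up, among them Col3a1, Col1a2, Spp1 and Sparc, down 1.96, 1.74, 1.68 and 1.42 (adjusted p = 0.325 with an estimated correlation). Markers of other cell types tested down as well, with falls in 2 of 9 stromal, 2 of 15 macrophage, 0 of 6 class II and 2 of 5 blood genes, and 8, 4, 0 and 3 adjusted over the list alone (adjusted p = 0.325, 0.53, 0.53 and 0.408 with an estimated correlation). Without GT 3 the macrophage, class II and blood lists had adjusted p = 0.0501, 0.0501 and 0.264, and class II also had 0.0504, 0.0618 and 0.0843 without HFD 2, HFD 3 and GT 2. NRF2 targets fell in 8 of 25, 13 adjusted over the list alone, with Gstm1 and Gpx3 down 1.39 and 1.33 (adjusted p = 0.325 with an estimated correlation). Male-biased genes rose in 4 of 17, 10 adjusted over the list alone (adjusted p = 0.325 with an estimated correlation). Immediate early genes fell in 3 of 12, 9 adjusted over the list alone, Gadd45b and Jund each by 1.33 (adjusted p = 0.325 with an estimated correlation). Respiratory chain genes fell in 4 of 29, 14 adjusted over the list alone, with Cox6c and Cox5a down 0.96 and 0.95 (adjusted p = 0.403 with an estimated correlation). The difference between short and long genes moved in the same direction, lying between 0.156 and 0.523 log2 in the HFD libraries and between -0.132 and -0.018 in the GT libraries, and Cox5a was in the set of genes high in HFD of both tissues. Lipid droplet genes fell in 5 of 18, 6 adjusted over the list alone, with Fabp4 down 1.89 and Lpl 0.97 (adjusted p = 0.408 with an estimated correlation, and 0.0992 at the preset correlation without GT 3). Cytokine genes fell in 4 of 14, 6 adjusted over the list alone, with Saa1 and Tgfb1 down 1.63 and 0.82 (adjusted p = 0.408 with an estimated correlation). Genes of the unfolded protein response rose in 1 of 21 and fell in 1, 9 and 2 adjusted over the list alone, Xbp1 up 0.93 and Trib3 down 0.82 (adjusted p = 0.403 with an estimated correlation). Clock genes rose in 2 of 19, 8 adjusted over the list alone with 1 down, among them Cry2 by 0.84 (adjusted p = 0.325 with an estimated correlation).

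Of 10670 liver genes 572 differed between extract and high-fat diet, 122 up and 450 down, and 2856 (26.8%) had nonoverlapping libraries against 10% by chance. The count was 321 without ND 1, 348 without ND 3, 349 without HFD 1, 43 without HFD 2, 100 without HFD 3, 262 without GT 1, 153 without GT 2 and 1240 without GT 3. Of 41 named calls, 12 held whichever library was left out, namely Hsd3b5, Gdf15, Gstm3, Cdkn1a, Scand1, Ccl2, Fgf21, Fabp4, Sparc, Jund, Gadd45b and Dpt. Among them, Scand1, Ccl2 and Jund were in the set of genes high in HFD of both tissues. Leaving out HFD 2 ended 29 of the calls, HFD 3 ended 21, GT 2 ended 14, GT 3 ended 6, GT 1 ended 5, ND 1 ended 3, and ND 2, ND 3 and HFD 1 ended 2 each. The share of rises depended on scaling, 21.3% as listed and 35.5% after quantile scaling.

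Against the normal diet, liver of mice given the extract held higher levels of 12 of 23 cholesterol synthesis genes and lower levels of 7 of 30 PPARA targets. Aacs, which feeds acetoacetate into lipid synthesis, was higher by 3.72 ± 0.26 at 42.9 ± 14.9 FPKM against 2.21 ± 0.411 (adjusted p = 9.53e-05). Cfd and Cyp2a5 were higher by 6.00 and 3.10, and the droplet gene Cidea stood at 18.02, 7.768 and 2.578 FPKM against 0.2598, 0.1134 and a library listed at 0. Lepr, the insulin-lowered Igfbp1, Ehhadh, Tff3 and Cyp4a31 were lower by 3.15, 2.98, 2.41, 2.41 and 2.33. Srebf1 rose from 21.6 ± 2.37 to 59.3 ± 8.81 (adjusted p = 0.0109), while Fasn and Pparg were up 1.33 and 0.92 and Pck1 and G6pc down 1.41 and 1.57. Of 23 cholesterol synthesis genes 12 rose, 18 adjusted over the list alone, with Msmo1, Insig1, Idi1 and Mvk up 2.16, 1.63, 1.34 and 1.14 (adjusted p = 0.183 with an estimated correlation). PPARA targets fell in 7 of 30, 14 adjusted over the list alone, among them Acot1 and Cyp4a10, down 1.97 and 1.56 (adjusted p = 0.443 with an estimated correlation). Genes of the unfolded protein response rose in 5 of 21, 9 adjusted over the list alone, with Manf up 1.67 and Calr up 1.00 (adjusted p = 0.343 with an estimated correlation). Clock genes rose in 5 of 19, 9 adjusted over the list alone with 2 down, including Ciart, Usp2 and Bhlhe40 at 2.67, 1.97 and 1.63 (adjusted p = 0.343 with an estimated correlation). Gluconeogenesis and amino acid genes fell in 5 of 14, 7 adjusted over the list alone, with Got1 down 1.74 (adjusted p = 0.343 with an estimated correlation). By list, 10 differed, 5 up and 5 down.

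Of 10670 liver genes 277 differed between extract and normal diet, 135 up and 142 down, and 2301 (21.6%) had nonoverlapping libraries against 10% by chance. The count was 49 without ND 1, 167 without ND 2, 64 without ND 3, 171 without HFD 2, 104 without GT 1, 171 without GT 2 and 428 without GT 3. Of 29 named calls, 15 held whichever library was left out, Aacs, Cfd, Lepr, Igfbp1 and Msmo1 among them. Leaving out ND 1 ended 13, ND 3 ended 12, GT 1 ended 8, ND 2 ended 6, GT 2 ended 5, HFD 2 ended 4, and HFD 1, HFD 3 and GT 3 ended 3 each, with Pck1 and Pparg among the calls lost.

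Liver genes called in both comparisons, for the high-fat diet and for the extract, mostly changed in opposite directions. Of genes up on the high-fat diet 323 were down with the extract, Gdf15, Cyp2b9 and Gstm3 among them, against 53.5 expected from independent calls, and 69 such as Hsd3b5, C8b and Egfr were down and then up, against 8.14. Called in the same direction were 2 up and 0 down. Lepr and Cfd were called on the high-fat diet and not between extract and high-fat diet. Since the same HFD libraries enter both comparisons, chance alone gives a negative correlation, which was -0.703 here against -0.614 to -0.361 in 100 simulations of unchanged groups. How many shared calls the common libraries give among changed genes was not tested, so part of the excess may come from them. The length trend of the HFD liver libraries, or a batch that coincides with HFD, could also give opposite changes in the 2 comparisons. Falls with the extract numbered 450 as listed and 216 after the length and GC correction. In adipose tissue without ND 1, 93 genes such as Timp1 and Postn went up and then down. Another 92 such as Cfd and Pck1 went down and then up, against 18.3 and 11.1 expected from independent calls. The shared HFD libraries make the calls dependent, and how much of this excess they give was not tested either. The adipose correlation without ND 1 was -0.49 against -0.488 to -0.382 in the simulations, at their edge. With all 9 adipose libraries it was -0.035 against -0.531 to -0.464. The simulations gave all libraries the same spread per gene, whereas ND 1 stood far apart from the others. The comparison with all 9 libraries therefore decides nothing. With all 9 libraries 0 genes were shared, as limma called 0 for the extract, where 467 had unadjusted p under 0.05.

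**Figure D4:**
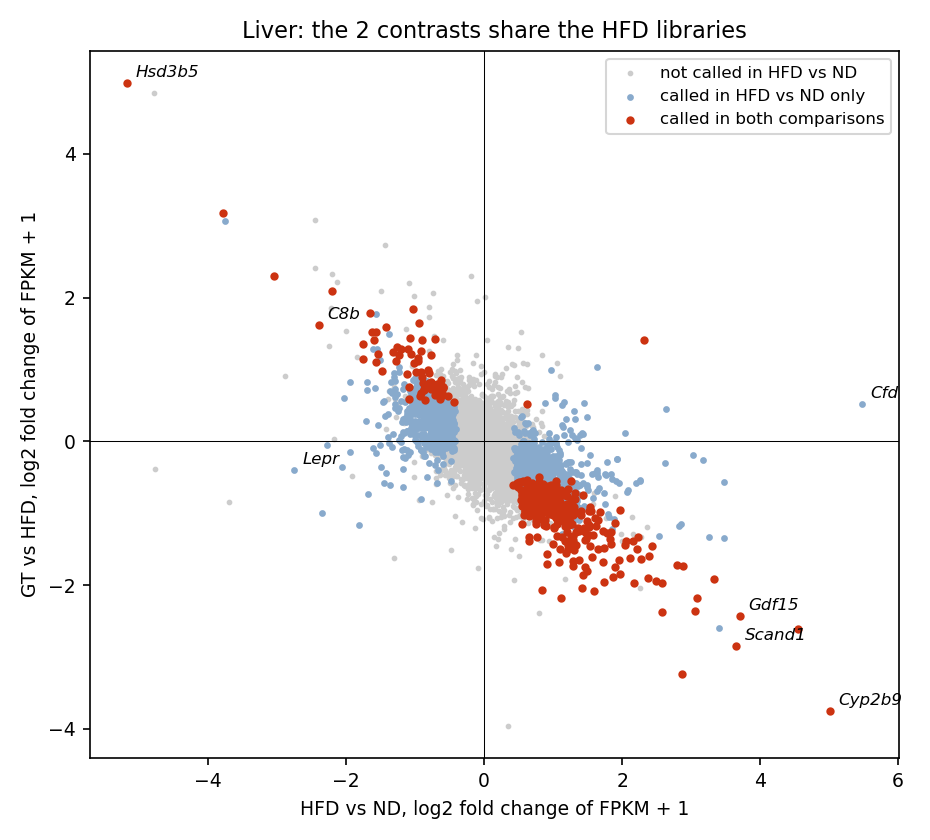
Liver log2 change of high-fat against normal diet (x) and of extract against high-fat diet (y), 1 point per gene. Gray genes were not called for the high-fat diet, blue were called there and red in both comparisons (392 genes in opposite directions).

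Single genes answered the high-fat diet differently in the tissues, Mmp12 and Cfd among them. Of 10042 genes measured in both tissues 857 had a tissue difference, 601 higher in adipose tissue and 256 lower. Mmp12 changed by 7.90 in adipose tissue and 1.23 in liver (difference 6.67, adjusted p = 0.000643), Adgre1 by 4.88 and -0.54, the clotting gene F7 by 5.03 and -0.39, Il1rn by 5.67 and 0.28, and the lysosomal lipase Lipa by 4.71 and -0.63. Cfd went the other way, -3.52 in adipose tissue and 5.48 in liver (difference -9.0, adjusted p = 2.21e-06), as did Cidea, Gsta4, Orm3 and Crygn. For the extract against the high-fat diet only Fgf21 had a tissue difference, 0.96 in adipose tissue and -2.07 in liver (3.02 ± 0.33, adjusted p = 0.0014), with 638 genes at unadjusted p under 0.05. With the replicate number as a block 0 genes had such a difference (Fgf21 adjusted p = 0.218), and the stricter filter, which left Fgf21 out, also gave 0. Crip2, Ifi27l2a, Inca1 and Fam89a (adjusted p = 0.0595) and, on the lower side, Dlg3, Wee1, Tk1, Apol7d and Zranb3 did not pass. Without adipose ND 1 the differences numbered 2145 and 386 of 9957 genes, the latter with Scd1 at 1.28 in adipose tissue and -1.28 in liver and Egfr at -0.25 and 2.09. For the high-fat diet the largest were then Mmp12 (5.68), F7 (5.46), Il1rn (5.23), Atp6v0d2 (5.08) and Zranb3 (4.63). On the lower side they were Cfd (-9.11), Plin4 (-4.44), Mogat1 (-4.44), Orm3 (-4.18) and Cyp2e1 (-4.02). Leaving out other libraries moved the 857 to 2568 without adipose ND 2, 2259 without adipose ND 3, 539, 487 and 354 without adipose HFD 1, 2 and 3, 428 and 401 without liver ND 1 and ND 3, and 502, 383 and 556 without liver HFD 1, 2 and 3. The single difference for the extract became 2 without liver GT 1 and 3 without liver GT 3. Any difference among the 3 diets was called for 415 adipose and 1662 liver genes, and for 11 and 1163 with the replicate number as a block. The adipose number was 2966 without ND 1, 1970 without ND 2, 29, 13 and 7 without HFD 1, 2 and 3, 219 without GT 1 and 41 without GT 2. The liver number was 542 without ND 1, 599 without ND 3, 1098, 376 and 880 without HFD 1, 2 and 3, and 3133 without GT 3.

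A set of genes was high in the HFD libraries of both tissues. Scand1 stood at 15.98, 10.75 and 14.03 FPKM in adipose HFD and at 12.25, 23.51 and 14.42 in liver HFD, against at most 1.641 and 2.177 in the other libraries of the tissues, adipose ND 1 excepted at 28.97. The ribonuclease Rnaset2b stood at 9.962, 8.724 and 9.685 in adipose HFD and 9.818, 5.548 and 7.107 in liver HFD, against 6.982 in adipose ND 1 and at most 0.5765 and 2.223 in the other adipose and liver libraries. Mrps34, H2afj, Jund and Cox5a were in the same set. Ccl2, Mmp12, Postn, Col3a1, Col1a2, Spp1 and Egr1, reported above as changes with diet or extract, were in it as well. In adipose ND 1, Ccl2 and Mmp12 stood at 0.1564 and 0.09591 FPKM. By a margin of 0.1 log2 over 17 libraries without adipose ND 1, 105 of 10042 genes lay higher in HFD of both tissues and 7 lower. Adipose ND 1 lay above the other ND and GT adipose libraries in 52 of the 105 (49.5%), against 30.2% of all genes. Those of the 105 with a known length had a median of 1218 bases, against 2311 over all genes. Short genes lay above long ones by 1.387 log2 in ND 1, against -0.314 to 0.046 in the other adipose libraries. The higher share in ND 1 may follow gene length, so it cannot tell whether ND 1 shares the HFD pattern.

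**Figure D5:**
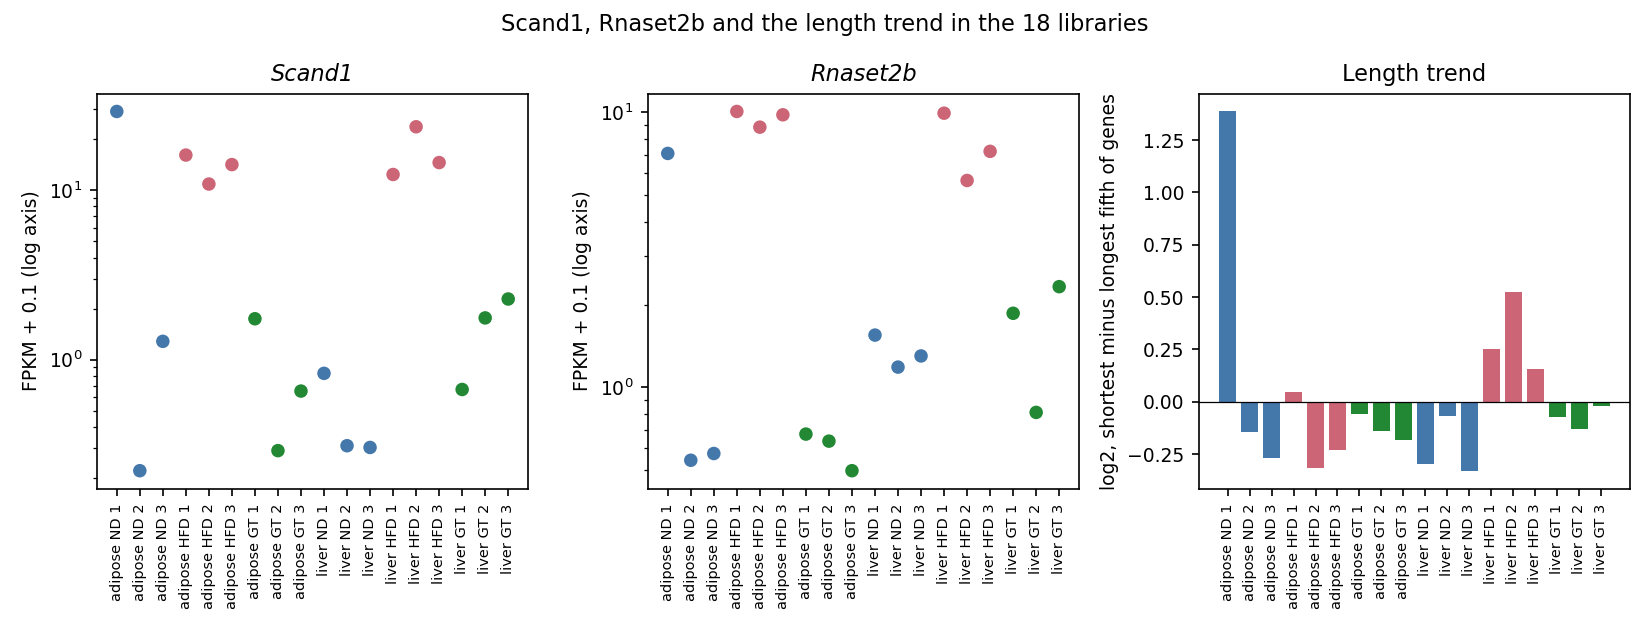
FPKM + 0.1 of Scand1 and Rnaset2b on a log axis in 18 libraries, and bars of the log2 difference of medians between the shortest and longest genes per library, each 20% of genes. For the bars, each gene was set relative to its mean over the libraries of the tissue.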

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

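Of the tests in this part, the female-biased gene test and the length and GC test had their predictions written before their results were seen, as had the other groupings of libraries, though the female-biased genes were listed after the data had been seen. The tests of testis markers, adipocyte markers, paralogs, hepatocyte markers and batch were chosen only after the result was seen.

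The response to the high-fat diet differed between the tissues by a test of the difference itself in 857 genes, against at most 952 in 99 other groupings of the libraries, with 2 of 100 groupings reaching the real number. Larger changes in adipose tissue were those of Mmp12 (difference 6.67), F7 (5.42), Adgre1 (5.41), Il1rn (5.39) and Lipa (5.34), with Mmp12 and Adgre1 being macrophage genes. Changes further down in adipose tissue were those of Cfd (-9.0), Cidea (-4.20), Gsta4 (-4.09), Orm3 (-3.99) and Crygn (-3.58). These 10 differences passed whichever library was left out. Their sizes rest on a fit with adipose ND 1. Without ND 1, Adgre1, Lipa, Cidea, Gsta4 and Crygn were no longer among the 5 largest named each way. For the extract 1 gene differed, Fgf21 (3.02), whose call ended with the replicate number as a block (adjusted p = 0.218), and other groupings gave up to 18 genes, with 5 of 100 reaching 1, so the number of calls is no more than other groupings give.

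The adipose library ND 1 carried RNA of testis and epididymis. RNA of several testis cell types may explain its content, as 95.8% of testis markers reached 10 FPKM. A mislabelled library without fat was argued against by adipocyte markers at a median of 8.52% of ND 2 and ND 3. That level cannot tell a fat sample mixed with other tissue from a mislabelled sample of other tissue that held some fat. Tnp1 at 707.3 FPKM in ND 3 and 604.2 in HFD 1 showed testis RNA in those libraries as well, at lower levels. Whether the tissue was mixed at dissection or at a later step stays open, and no biological explanation was tested.

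Male-biased liver genes such as Hsd3b5, Serpina1e and Cyp4a12b were lower on the high-fat diet and higher again with the extract, of which only Hsd3b5 kept its call with the extract whichever library was left out. Reads shared between paralogs were argued against as the whole cause of the fall, as the 5 genes without a near-identical copy had a median of -1.548. For the rise with the extract they stay open, as 3 of these 5 were higher and 2 lower, with a median of 1.286 and quartiles of -0.363 and 1.619. Of the 3 only C8b was called (1.62, adjusted p = 0.0144), and Elovl3 was among the 2 (-0.36, adjusted p = 0.593). Dilution of hepatocyte RNA was argued against by hepatocyte markers at a median of -0.02, with quartiles of -0.446 and 0.367. A shift of the sex-dependent programme stays open, because 9 of 15 female-biased genes were under the filter and the other 6 had a median of -0.114. The rise of Cyp2b9 and Cyp2a4, which are higher in females, was known before that test and adds no weight.

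Genes such as Scand1, Rnaset2b and Rnaset2a were high in HFD libraries of both tissues and in adipose ND 1. After a correction for gene length and GC content, 67.3% (70 of 104) stayed separated in both tissues. This lies between the limits set for and against and cannot tell. How many genes another correction would move under a margin of 0.1 log2 was not tested. In adipose tissue the difference between short and long genes was 0.046, -0.314 and -0.231 log2 in HFD, against -0.267 to -0.058 in ND 2, ND 3 and GT. That argues against gene length as the cause of high HFD values in that tissue. A library batch that coincides with the HFD groups could give high levels in HFD of both tissues. No other grouping had a gene separated by over 0.5 in both tissues, where the real value was 9 genes and the highest other 0, and 1 of 100 groupings reached it. No label names a batch, and a batch that coincided with HFD could not be told from the diet here. An effect of the diet on these genes therefore stays open. Ccl2, Mmp12, Postn, Col3a1, Col1a2 and Spp1 are in the set, so these groupings cannot tell batch from diet for them either. Adipose ND 1 had Scand1 at 28.97 FPKM on a normal diet, but its testis RNA could bring that value, so it decides nothing.

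In other groupings of 3 against 3 libraries, 10 splits are too few for a share under 0.05. High-fat against normal diet gave 777 adipose genes and at most 529 in another split, and 1980 liver genes and at most 0. Extract against high-fat diet gave 0 adipose genes and at most 0, so 10 of 10 splits reached it, and 572 liver genes and at most 1. Extract against normal diet gave 88 adipose genes and at most 0, and 277 liver genes and at most 1. In each of the other 5 cases the real split was the 1 reaching its number. For any diet difference, 2 of 100 groupings reached the real 415 in adipose tissue, where the highest other was 481, and 1 of 100 the real 1662 in liver, where the highest other was 812. These groupings took no account of the replicate number, and with it as a block the adipose number was 11.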

How the results depend on the processing

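The fits without libraries of another tissue, the length and GC correction and the list tests at equal FPKM totals were tests chosen only after the data had been seen. Leaving out each library in turn gave 59 to 3527 adipose genes for high-fat against normal diet, 0 to 218 for extract against high-fat diet, 0 to 2544 for extract against normal diet and 7 to 2966 for any diet difference. The liver ranges were 460 to 3367, 43 to 1240, 49 to 428 and 376 to 3133. Tissue differences ranged from 354 to 2568 for the high-fat diet and from 1 to 386 for the extract, and the adipose overlap of the effects of high-fat diet and extract, 0 with all 9 libraries, was 185 without ND 1. For high-fat against normal diet, extract against high-fat diet and extract against normal diet, lists ranged from 8 to 16, 12 to 17 and 10 to 12 in adipose tissue and from 14 to 17, 11 to 17 and 9 to 17 in liver. Scd1 in adipose tissue on the high-fat diet turned from 0.27 to -1.41 without ND 1, was 1.18 without ND 2, and turned to -1.46 without the 3 libraries with testis transcripts, and Pck1 with the extract against the normal diet turned from 0.05 to -1.52 without ND 1 and was 0.86 without ND 2. Where no cause is named for a change in this part, the cause was not tested.

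Without a filter, extract against normal diet gave 22 adipose and 143 liver genes, extract against high-fat diet 262 liver genes, the liver overlap 172, and tissue differences 1438 and 3, while the stricter filter gave 504 and 0. At equal FPKM totals, extract against high-fat diet gave 209 liver genes, extract against normal diet 147, any diet difference 1022, the overlap 138, and the tissue difference for the extract 2. That scaling also moved the share of rises in liver from 64.0% to 41.6% for the high-fat diet and from 21.3% to 32.5% for the extract against it, and in tissue differences from 70.1% to 88.8%. Quantile scaling gave 187 adipose genes for extract against normal diet, and 35.5% of rises in liver for extract against high-fat diet. The length and GC correction gave 228 adipose genes for extract against normal diet and 352 liver genes for extract against high-fat diet, of which 38.6% rose. Shifts of the median change over 0.1 came with equal totals in adipose tissue (0.277 and 0.236 against the normal diet) and liver (-0.185 for the high-fat diet and 0.124 for the extract against it), with quantile scaling (0.158 and 0.177 for the extract in adipose tissue), with no filter (-0.17 and -0.142), the stricter filter (0.116 and 0.132), without ND 1 (-0.117 and -0.131), without ND 3 (0.235 and 0.219) and with the length and GC correction (0.159, extract against high-fat diet), these last all in adipose tissue.

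Fitting 18 libraries together gave 2842, 26, 2942 and 2734 adipose genes for high-fat against normal diet, extract against high-fat diet, extract against normal diet and any diet difference, and 305, 76, 81 and 275 liver genes. A pooled variance of both tissues stands behind these numbers by construction. With only the compared diets in the fit the first 3 were 317, 920 and 0 in adipose tissue, and extract against high-fat and normal diet gave 175 and 99 in liver. Without the 3 adipose libraries with testis transcripts the 4 numbers were 3738, 170, 1238 and 3081, and without the 2 liver libraries with most muscle transcripts extract against high-fat and normal diet gave 242 and 438. The libraries left single in a diet by this are assumed to vary like the others.

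With the replicate number as a block, high-fat against normal diet gave 337 adipose genes, extract against normal diet 3, any diet difference 11, and in liver extract against high-fat and normal diet gave 306 and 141, while tissue differences numbered 409 and 0. Libraries share only a number in these blocks. Residual correlations of libraries of the same number ran from -0.069 to 0.643 between adipose diets, from -0.301 to 0.418 between liver diets and from -0.241 to 0.284 between tissues. Correlations over 0.1 were found in 6 of 9 adipose pairs of the same number against 5 of 18 of different numbers. The counts were 4 of 9 against 7 of 18 in liver, and 2 of 9 against 6 of 18 between tissues. The adipose value of 0.643 joined ND 1 and HFD 1, which both held testis RNA. ND 2 and HFD 3, of different numbers, reached 0.66. Whether the numbers mark paired samples in adipose tissue therefore cannot be told from these values.

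With an estimated correlation 0 lists passed in each of the 6 comparisons. By fry 0 and 5 adipose lists passed for extract against high-fat and normal diet, and 5 and 6 liver lists. At equal FPKM totals 11, 17 and 11 adipose lists and 16, 15 and 11 liver lists passed. Over the settings other than leaving out a library, 1242 of 1419 values of named adipose genes and 1283 of 1439 of named liver genes kept direction and side of the threshold, and with a library left out 983 of 1170 and 1007 of 1176 did. Read numbers, and with them the limit set by depth, were not analysed here. The spread between the 9 adipose libraries limits what the fit with ND 1 can show, as simulated changes of log2 1 were recovered in 0% and 4% of genes. That simulation gave the spread of the fit with ND 1 to every diet, and recovery without ND 1 was not simulated. Without ND 1 the calls rose from 777 to 3527 for high-fat against normal diet and from 0 to 218 for extract against high-fat diet.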

Other observations

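The clock test in this part was chosen only after the result was seen.

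Some further genes differed. In liver, hemoglobin Hba-a2, which has a near-identical copy, was up 1.84 on the high-fat diet, and the lipogenic regulator Thrsp was up 3.03 and stayed 2.84 above the normal diet with the extract (adjusted p = 0.00505). The endothelial receptor Kdr was down 0.84 in liver on the high-fat diet and 0.80 with the extract against the normal diet. Its call with the extract ended without any 1 of the ND and HFD libraries or GT 1. Elovl3, an elongase of very long fatty acids and a male-biased gene, was 1.86 lower in liver with the extract than on the normal diet (adjusted p = 0.0256). This call ended without any 1 of the ND libraries, GT 1 or GT 3. The stromal gene Dpt fell by 1.71 in liver with the extract against the high-fat diet, and Apoa4, of the lipid droplet list, by 1.94. The call of Apoa4 ended without any 1 of the ND libraries, HFD 2, HFD 3, GT 2 or GT 3. In adipose tissue on the high-fat diet, Scd2 was up 2.54, Ucp2 2.88, Hmox1 3.30 and Otop1 2.31, while asparagine synthetase (Asns) fell by 1.65. Calls of Ucp2, Hmox1 and Asns ended without HFD 3, those of Ucp2 and Hmox1 also without HFD 1, and that of Hmox1 without HFD 2. Without ND 1, 5 of 16 adipose stromal and mesothelial genes were lower with the extract than on the normal diet and 0 higher, 7 and 1 adjusted over the list alone, among them Gpm6a, Lrrn4, Msln and Wt1 at -1.58, -1.60, -1.34 and -1.18 (list adjusted p = 0.00143, and adjusted p = 0.471 with an estimated correlation). With all 9 libraries 0 of 16 passed and the list did not pass (adjusted p = 0.0797). These genes were chosen after their values were seen.

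In liver, clock genes such as Per3 (1.09, adjusted p = 0.0749) and Per2 (1.08, adjusted p = 0.156) did not pass between extract and high-fat diet, while Cry2 rose by 0.84. A clock shift shared by both tissues would move clock genes alike in liver and fat. Across 19 clock genes the changes with the extract had a rank correlation of 0.24 between liver and adipose tissue without ND 1, with 10 genes of the same sign, which lies between the limits set and cannot tell. Different collection times could give such a pattern, and collection times were not analysed here. In adipose tissue without ND 1, Arntl fell by 0.87 and Npas2 by 0.88 with the extract. Usp2 changed by -0.86 there and by 0.99 in liver, and stood at 14.61 FPKM in adipose HFD 1 against 3.141 and 2.889 in HFD 2 and HFD 3. It was also high in ND 1 and ND 3 (343.9 and 57.91). As HFD 1 held testis RNA like these, such RNA may enter the adipose change of Usp2. The rank correlation without Usp2 was not computed.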
